A study of Escherichia coli K-12 with 2 samples.

How the data were processed

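RNA that copurified with an MS2-tagged 3'ETSleuZ or with the untagged RNA was measured by small RNA sequencing in 1 library per group. Per the labels' protocols, lysates of arabinose-induced MG1655 cells were passed over 100 µL of amylose resin carrying 200 pmol of MS2-MBP protein, washed with 8 mL of buffer, eluted with 15 mM maltose, DNase treated and made into libraries with a kit for small RNA fragments. Both libraries are labelled with exponential and stationary phase. The table has 1 column of counts per library, so the phases could not be analysed apart. Every column was used.

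The deposited values are read counts per gene or intergenic region, per the file headers, with whole numbers from 1 upward. Reads were aligned with Bowtie, per the submitters' processing notes. The aligner version, genome build, counting rule, use of strand and treatment of reads with several matches are not given in the sources used here, and no coordinates are therefore printed. The authors also deposited normalized values and their ratio. Dividing the counts by the normalized values gave 1 constant per library, 2968425 for the tagged and 1814326 for the untagged one, here called the authors' library totals. What they count is not given in the sources used here. The listed counts came to 73.9% and 46.9% of these totals. The deposited ratio differed from the quotient of the normalized columns by at most 0.000733%.

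No count below 1 is listed. In the untagged library 1343 features stood at 1 and 493 at 2, and in the tagged library 667 and 464, so that a listed 1 may stand for 0. Interval bounds that this would move were therefore computed with 0, and a feature listed at 1 in the untagged library has no upper bound. Some reads are counted in more than one feature: in 8 pairs of neighbouring or overlapping features with at least 500 tagged counts each, both libraries' counts differed by at most 10%. Overlapping and antisense genes, and near-identical copies such as the rRNA genes, are uncertain for that reason. The duplicated counting also enters the totals.

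Names were taken from the table. A reference gene table of the MG1655 assembly ASM584v2 was used only for gene class and for which annotated noncoding RNAs lie within a gene or between its neighbours; 4172 of 4194 gene names matched it and 22 did not. CPM values were computed on the sum of all listed counts of a library. The ratio is tagged over untagged, with a pseudocount of 0.5 on each count, and its 95% interval is the exact Clopper-Pearson interval of the tagged share of a feature's counts. Shares of a library have Clopper-Pearson intervals. All cover counting error only, and reads amplified by PCR are not independent molecules. With 1 library per group no test between groups was made. In its place a feature was called enriched at a ratio of at least 4, an interval wholly above 2 and at least 50 counts over both libraries, and depleted by the mirrored rule. A list median was set against 10000 random lists of the same size, each member drawn from the 50 features nearest to it in mean CPM.

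The gene lists, the size rule and the rule for named genes were fixed before the data were examined. The lists hold base-pairing sRNAs, housekeeping RNAs, antisense RNAs, tRNAs, the glyW-cysT-leuZ transcript, rRNAs, and mRNAs of ribosomal proteins, RyhB targets, RybB targets, iron uptake with iron-sulfur cluster assembly, sigma E, stationary phase, arabinose, maltose, RNA chaperones and ribonucleases, and abundant genes. Named are the 20 features with the highest lower bound and the 10 with the lowest upper bound, the listed sRNAs and housekeeping RNAs, features of the leuZ transcript, hfq, rne, malE and araB, the 5 features with the most counts in each library, and the 2 members with the most counts of every other list. Features beyond this rule, such as those with an annotated noncoding RNA inside, were chosen after their values were seen.

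The alternatives were trimmed-mean (TMM) factors from edgeR 4.0.16, median-of-ratios factors from DESeq2 1.42.0, totals without tRNA and rRNA or of mRNA features, a pseudocount of 5, other count minimums and ratio thresholds, and leaving out near-identical copies. The authors' library totals, the total without the yecA_leuZ region, listed counts of 1 set to 0 and the removal of read-sharing neighbours were added after the data were seen. Neither edgeR nor DESeq2 was used for a test. The rule was tested on simulated Poisson counts for 7041 features with 200 changed. More features were raised than lowered, so that scaling by totals turned a simulated ratio of 4 into 3.30 and one of 0.25 into 0.206. The rule called 2 of 25 features raised 4-fold, 24 of 25 lowered to 0.25, 23 of 25 raised 8-fold, 23 of 25 lowered to 0.125, 25 of 25 raised 16-fold and none of 2577 unchanged features past the minimum, and 96.4% of the intervals held the simulated ratio. The simulation has no variation between libraries beyond counting, and its intervals did not take a count of 1 as 0. In the data the median ratio of features past the minimum was 0.544, a larger downward shift than in the simulation. Typical features thus lay nearer to the limit for depletion than to that for enrichment. The simulated calls therefore give no rate of false calls for the data, above all for depletion. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.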

Results

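The data came from an affinity purification of a bacterial RNA and of the RNAs bound to it. The bait was 3'ETSleuZ, the external transcribed spacer that is released from the 3' end of the glyW-cysT-leuZ tRNA transcript of Escherichia coli and that is known as a sponge for small regulatory RNAs (sRNAs). In the tagged group the bait carried the MS2 aptamer, an RNA hairpin that an MS2 coat protein fused to maltose-binding protein holds on amylose resin. In the control group the same bait had no aptamer, so that RNA recovered there marks the background of the column. Both baits were expressed in strain MG1655, a standard K-12 laboratory strain, from an arabinose-inducible promoter with 0.1% arabinose for 10 min. Cells were harvested in exponential phase at an OD600 of 0.5 and in stationary phase at 1.3, and each library is labelled with both phases. Each group had 1 library, and the difference between the groups therefore had no replicate check. No p-value is given for any gene, and the 95% intervals below are exact conditional binomial intervals that cover counting error only.

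The table listed 7041 features, of which 4194 were genes and 2847 were intergenic regions. The tagged library held 2194990 counts and the untagged library 850655. The composition of the eluates differed. Features annotated as sRNA or other noncoding RNA took 17.4% of the tagged counts (Clopper-Pearson 95% interval 17.4 to 17.5) and 1.86% of the untagged counts (1.84 to 1.89). This class leaves out the transfer-messenger RNA ssrA, which took a further 0.115% of the tagged and 0.584% of the untagged counts. Ribosomal RNA took 6.84% (6.81 to 6.87) and 19.5% (19.4 to 19.5), and protein-coding features took 32.7% (32.7 to 32.8) and 50.3% (50.2 to 50.4). These are classes of features and not of RNA, and some reads are counted in more than 1 class. The protein-coding share includes aceK (7.69% of the tagged counts), which holds an annotated sRNA, and arcB (1.75%), which overlaps the sRNA gene arcZ. The noncoding share includes the antisense RNA gene arrS (5.88%). The share of tRNA was 0.64% in both libraries, but without leuZ it was 0.118% (0.114 to 0.123) of the tagged and 0.614% (0.598 to 0.631) of the untagged counts. The 10 features with the most counts took 48.1% of the tagged library and 29.1% of the untagged one.

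The bait region itself was the feature with the most counts in the tagged library. The intergenic region between yecA and leuZ, in which the current annotation places the 3'ETS of leuZ, took 13.6% of the tagged counts (298231) and 2.34% of the untagged counts (19934). Its ratio of CPM (counts scaled to the library total), tagged over untagged, was 5.80 (5.72 to 5.88). The table does not separate plasmid-borne from chromosomal bait RNA. The adjoining tRNA gene leuZ had 11447 counts against 225, a ratio of 19.7 (17.3 to 22.6). Its counts may include bait reads that cross the boundary, so it may not be separate from the bait region. The other tRNA genes of the transcript did not follow it: cysT had 28 counts against 17, a ratio of 0.631 (0.337 to 1.24), and glyW had 11 against 21, a ratio of 0.207 (0.0884 to 0.440). The spacer between leuZ and cysT had 25 against 6 counts.

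The series asks which sRNAs copurify with the tagged bait. Base-pairing sRNAs, which act on mRNAs mostly with the RNA chaperone Hfq, stood far above the other features in the tagged library. Of 34 sRNAs on a list fixed before the data were examined, 30 were in the table under their own names. At least 50 counts over both libraries were found for 26. The listed cpxQ, micL and rybA had no feature of their own, and regions that hold them are given under the other observations. A ratio of 2 or more was found for 19 of these 26, a ratio of 0.5 or less for 2, and a value in between for 5. The median log2 ratio of the list was 2.86, a 7.28-fold higher level in the tagged library, against -0.88 for all 2626 features past the minimum. The level depended on the scaling: with trimmed-mean scaling the list median was 3.63 and that of all features -0.11. It lay above the medians of all 10000 random lists of the same size matched on expression, 95% of which fell between -1.84 and -0.68. That percentile describes these 2 libraries and does not test the conditions. The list as a whole took 11.5% of the tagged counts and 1.31% of the untagged counts.

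The sRNAs with the highest ratios were OmrB, which represses mRNAs of outer membrane proteins, and RydC, an activator of the cfa mRNA. OmrB had 8853 counts against 57, a ratio of 59.7 (46.4 to 79.5), and rydC had 24721 against 179, a ratio of 53.4 (46.2 to 62.4). RybB, the sigma E dependent repressor of porin mRNAs, and RyhB, the sRNA of iron limitation, are the known partners of the sponge. The ratio of rybB was 18.3 (14.5 to 23.9), from 3194 counts against 67, the third highest of the 26. The ratio of ryhB was 17.4 (7.53 to 72.5), the fifth highest, and its wide interval comes from only 202 counts against 4. These intervals leave out the choice of scaling: with trimmed-mean scaling rybB stood at 31.3, outside its interval, and ryhB at 29.7. ArcZ, an activator of rpoS translation, and GcvB, a repressor of amino acid transporter mRNAs, had about the same ratio at much greater depth: 17.2 (16.1 to 18.4) for arcZ with 38692 tagged counts and 17.0 (16.2 to 17.9) for gcvB with 64789. The ryeA feature stood between rybB and ryhB at 18.2 (15.2 to 22.3); it overlaps the antisense sRNA gene sdsR, and the reads of the pair cannot be told apart without knowing whether counting used the strand. The sdsR feature itself had 27 counts against 6. The cell division inhibitor dicF had a ratio of 14.0 (12.4 to 15.9), the curli and motility regulator mcaS 13.4 (12.2 to 14.7), and spf, the gene of an sRNA of carbon catabolite repression, 9.87 (8.79 to 11.2).

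**Figure D1:**
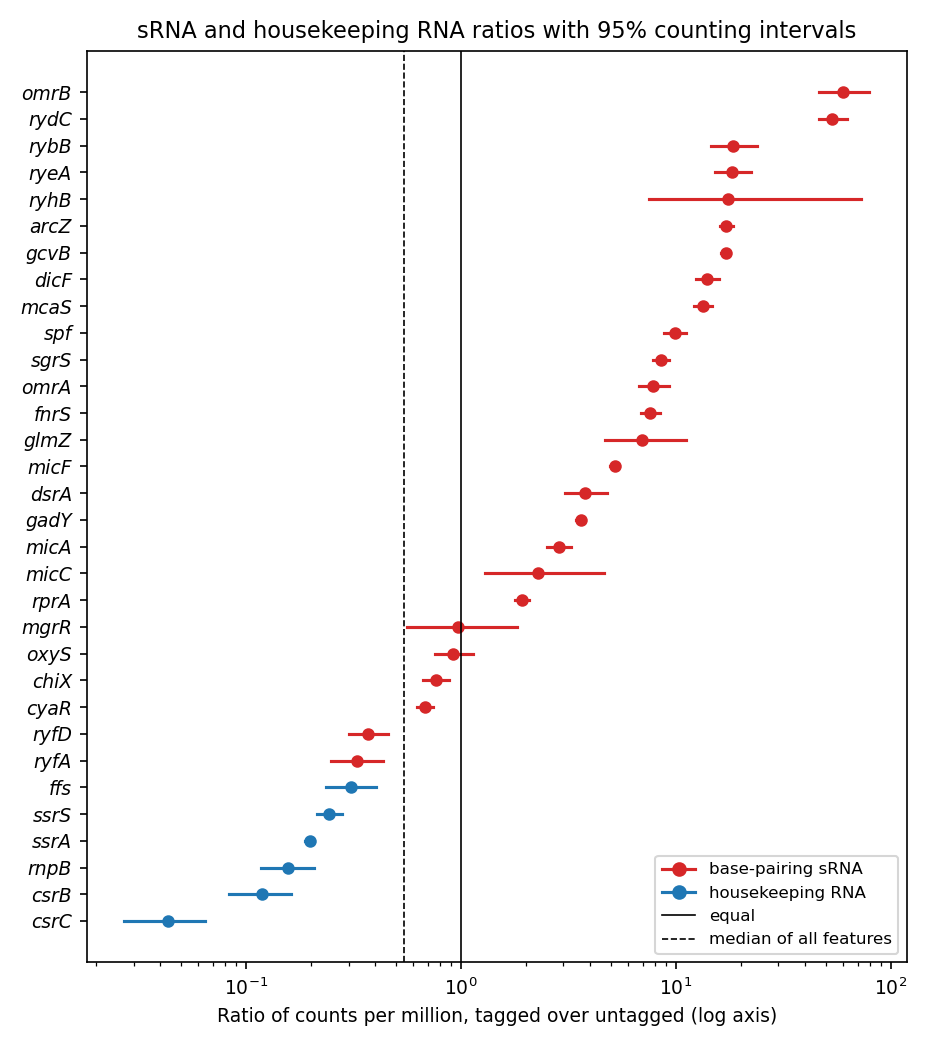
Ratio of CPM in the tagged over the untagged library (log axis) for the 26 base-pairing sRNAs past the count minimum (red) and the 6 housekeeping RNAs (blue), with 95% counting intervals from 1 library per group. The sRNAs run from 0.33 for ryfA to 59.7 for omrB, and the 6 housekeeping RNAs lie below the median of all features (dashed line).

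Further sRNAs lay between these and the background. The ratio was 8.49 (7.81 to 9.26) for sgrS, 7.84 (6.71 to 9.26) for omrA, 7.62 (6.91 to 8.44) for fnrS, 6.95 (4.70 to 11.2) for glmZ and 5.20 (4.95 to 5.46) for micF. OmrA and OmrB are encoded side by side and share much of their sequence, so that the gap between their ratios depends on how reads common to both were assigned. Ratios were 3.79 (3.06 to 4.79) for dsrA, 3.60 (3.42 to 3.80) for gadY, 2.84 (2.52 to 3.24) for micA, 2.28 (1.30 to 4.62) for micC and 1.93 (1.79 to 2.08) for rprA. Not all well-known Hfq-dependent sRNAs were among the enriched. The ratio was 0.974 (0.563 to 1.81) for mgrR, 0.923 (0.758 to 1.13) for oxyS, 0.763 (0.664 to 0.880) for chiX and 0.681 (0.623 to 0.745) for cyaR, all 4 below 1 here and above 1 when scaled by trimmed means, median ratios, mRNA totals or the authors' library totals. The lowest sRNAs were ryfD at 0.371 (0.300 to 0.458) and ryfA at 0.330 (0.249 to 0.436). In the reference ryfD overlaps the protein-coding gene clpB, at 0.333 (0.290 to 0.384), and ryfA overlaps sseB, at 0.270 (0.229 to 0.319). Likewise chiX overlaps ybaP, and their counts differ by at most 7.57%. The reads of these sRNAs cannot be told apart from those of the overlapping genes. Fewer than 50 counts were found for sdsR, rydB, ryjA and glmY.

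The stable RNAs that do not act by base pairing on mRNAs went the other way. All 6 housekeeping and protein-titrating RNAs had ratios of 0.5 or less, with a median log2 ratio of -2.50, at percentile 0.09 of matched random lists. The csrC RNA, which titrates the RNA-binding protein CsrA, had the lowest ratio of them at 0.0434 (0.0270 to 0.0646), and its partner csrB stood at 0.118 (0.0838 to 0.162). The RNase P RNA rnpB had a ratio of 0.157 (0.118 to 0.206), the transfer-messenger RNA ssrA 0.198 (0.188 to 0.207), the RNA polymerase regulator ssrS 0.244 (0.214 to 0.279) and the signal recognition particle RNA ffs 0.309 (0.236 to 0.401). These 6 ratios stayed below 1 under each of the 6 other scalings. Of the 31 tRNA genes other than leuZ with at least 50 counts, 27 had ratios of 0.5 or less, and the tRNA list with leuZ had a median log2 ratio of -2.09 at percentile 0. With trimmed-mean scaling 19 of the 32 tRNA genes were at 0.5 or less. The list of antisense and type I antitoxin RNAs, which did not include the abundant antisense RNA arrS, was too thinly covered for a group statement: 14 of 22 were listed and only sokX passed the minimum, at 4.38 (2.07 to 13.3). The next of them by counts was sibB, with 18 against 27.

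**Figure D2:**
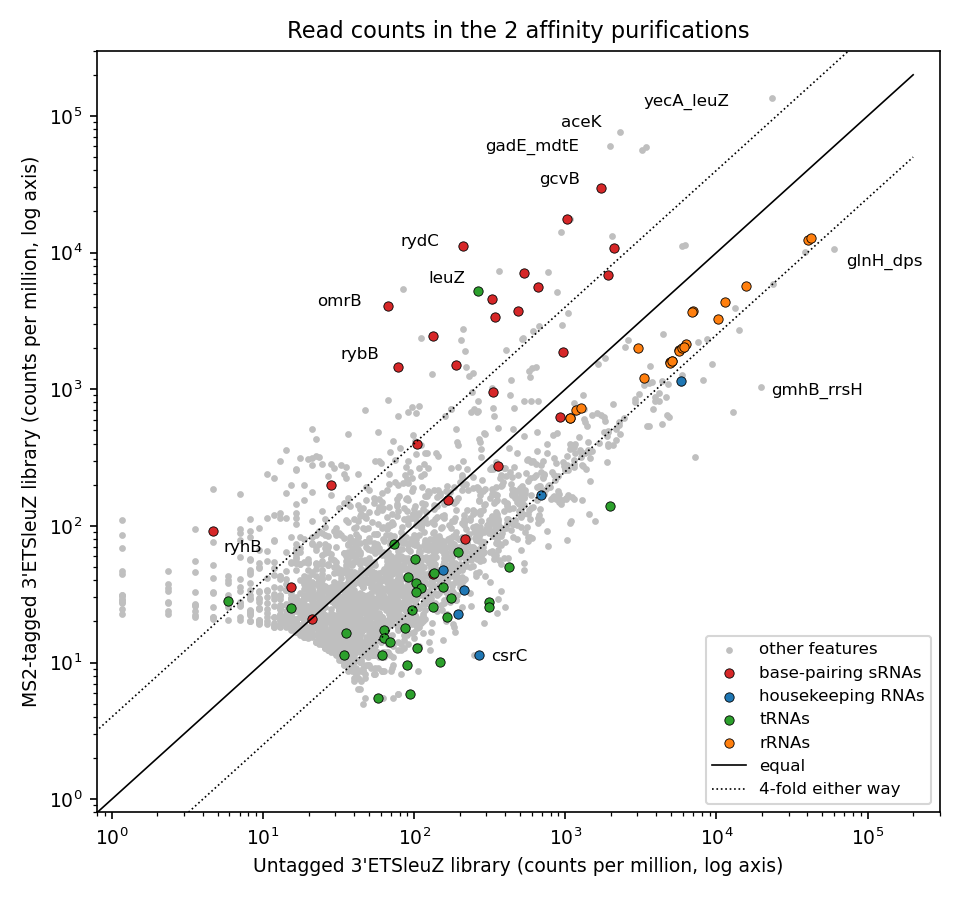
CPM of each feature with at least 50 counts in the untagged library (x, log axis) and the tagged library (y, log axis), with base-pairing sRNAs, housekeeping RNAs, tRNAs and rRNAs coloured. Points above the upper dotted line have a ratio over 4; they include yecA_leuZ at 5.80, aceK at 33.6 and rydC at 53.4.

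Across all features, 184 met the rule for enrichment with the tagged bait, which asks for a ratio of at least 4, an interval wholly above 2 and at least 50 counts, and 381 met the mirrored rule for depletion. These calls follow a size rule and are not tests. The enriched features were 95 intergenic regions, 68 protein-coding genes, 18 noncoding RNA genes, 2 pseudogenes or mobile elements and 1 tRNA gene (leuZ). The split between the directions depended on the scaling. With trimmed-mean scaling 338 features were enriched and 78 depleted, with median-of-ratios factors 349 and 72, with mRNA totals 303 and 109, with the authors' library totals 312 and 101, and with totals that leave out the bait region 208 and 271. All 184 were also enriched under each of these 5 scalings, which holds by construction because each of them raises every ratio. Totals that leave out tRNA and rRNA lower every ratio and went the other way. They gave 155 enriched, by construction all among the 184, and 531 depleted.

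Of the 20 features with the highest lower bound of the ratio, 9 were intergenic regions, 7 noncoding RNA genes, 3 protein-coding genes and 1 the leuZ gene. The intergenic region between cybB and rydC stood at 63.7 (50.9 to 82.0). The region between omrA and omrB had 243 counts against a listed 1, a ratio of 62.9 with a lower bound of 16.7 and no upper bound. Both regions adjoin listed sRNA genes (rydC, omrA and omrB), so they may not be loci separate from these. The protein-coding feature aceK, which encodes isocitrate dehydrogenase kinase/phosphatase and holds the annotated sRNA aceK-int, had 168872 counts against 1949 and a ratio of 33.6 (32.1 to 35.1). The region between gadE and mdtE, in the acid resistance island and with the annotated sRNA gadF, had 131915 against 1681 and a ratio of 30.4 (29.0 to 31.9). In the same island the antisense RNA gene arrS had a ratio of 17.2 (16.6 to 17.8), and the region between hdeD and arrS, whose counts differ from those of arrS by at most 5.95%, stood at 17.6 (17.0 to 18.3). The sensor kinase gene arcB, at 16.4 (15.4 to 17.6), overlaps arcZ and differs from it by at most 4.07% in counts, so that these features largely repeat the same reads. The endonuclease gene cho had a ratio of 21.0 (17.2 to 26.1). Ratios were 35.5 (15.5 to 147) for the region between ydgK and rsxA, from 412 against 4 counts, 24.5 (14.5 to 49.6) between rnd and fadD, 23.6 (15.3 to 41.0) between umuC and dsbB, 20.2 (18.0 to 22.7) between yodB and serU, and 15.1 (14.1 to 16.2) between glnL and glnA, where the sRNA glnZ is annotated.

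The 10 features with the lowest upper bound of the ratio were mostly regions of rRNA operons and small genes. The regions beside rrsG, rrsD and rrsH stood at 0.0437 (0.0404 to 0.0473), 0.0522 (0.0494 to 0.0551) and 0.0532 (0.0509 to 0.0556), and the region beside rrsE at 0.0765 (0.0645 to 0.0900). The tRNA gene ileU, which lies inside an rRNA operon, had a ratio of 0.0711 (0.0627 to 0.0802), and the spacer between alaU and ileU 0.0690 (0.0598 to 0.0791). The remaining members of this set were csrC, the region between trpR and yjjX at 0.0465 (0.0289 to 0.0693), the nucleoid protein gene stpA at 0.0647 (0.0475 to 0.0854) and the leader peptide gene pheL at 0.0660 (0.0477 to 0.0883). Mature rRNA was less extreme, with ratios from 0.316 to 0.383 for the 7 small-subunit genes, from 0.303 to 0.348 for the 7 large-subunit genes and from 0.317 to 0.658 for the 8 rrf genes. In the rRNA list as a whole, 15 of 22 genes had ratios of 0.5 or less, and its median log2 ratio of -1.54 lay at percentile 54.5 of matched lists; with trimmed-mean scaling none of the 22 was at 0.5 or less. The copies are near identical, and rrlG (ratio 0.303) and rrlD (0.308) carried the most reads. The most abundant feature of the untagged library was the region between glnH and dps, with 5.98% of its counts and a ratio of 0.177 (0.175 to 0.180); dps, which encodes the DNA-binding protein of starved cells, stood at 0.264 (0.259 to 0.268).

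The mRNAs listed as targets of RyhB and RybB did not stand apart from features of similar abundance in the eluate. Of 16 RyhB target mRNAs past the minimum, 1 had a ratio of 2 or more and 8 of 0.5 or less. Their median log2 ratio was -0.99, at percentile 62.3 of matched lists. The 2 members with the most counts were the fumarate reductase gene frdA at 0.266 (0.240 to 0.293) and the succinate dehydrogenase gene sdhA at 0.444 (0.392 to 0.504). Of 7 RybB target mRNAs, 6 had ratios of 0.5 or less, with a median of -1.62 at percentile 28.0; with trimmed-mean scaling 2 of the 7 RybB targets and 2 of the 16 RyhB targets were at 0.5 or less. The porin genes ompC and ompA stood at 0.301 (0.286 to 0.318) and 0.252 (0.230 to 0.277).

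Other mRNA groups lay at or below the median feature. Of 50 ribosomal protein mRNAs, 42 had ratios of 0.5 or less and none reached 2; their median was -1.75, at percentile 0.04, with rplD at 0.246 (0.241 to 0.252) and rplC at 0.297 (0.289 to 0.306). With trimmed-mean scaling 23 of the 50 had ratios of 0.5 or less and 2 reached 2. The list of iron uptake and iron-sulfur cluster mRNAs had 5 measurable members, with a median of -1.92 at percentile 1.48. The 2 with the most counts, sufS at 0.234 (0.167 to 0.323) and sufC at 0.407 (0.281 to 0.589), encode iron-sulfur cluster assembly proteins and not uptake proteins. The 13 abundant mRNAs taken as background had a median of -1.84 at percentile 4.66, with tufA at 0.231 (0.220 to 0.243) and acpP at 0.226 (0.214 to 0.239). The medians were -1.15 for 10 sigma E mRNAs (percentile 33.8; bamA at 0.353 and surA at 0.410), -1.15 for 14 stationary phase mRNAs (percentile 57.2; dps at 0.264 and gadC at 0.930) and -1.51 for 12 mRNAs of RNA chaperones and ribonucleases (percentile 9.80; eno at 0.243 and pnp at 0.305). The mRNA of Hfq stood at 0.361 (0.243 to 0.533) and that of RNase E, rne, at 0.201 (0.165 to 0.244).

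Genes of the arabinose and maltose systems were also measured. Arabinose was given to both groups alike, and maltose served to elute RNA from the resin after lysis. The 9 arabinose mRNAs had a median of -1.00 at percentile 72.3. The putative transporter gene araJ stood at 3.11 (2.89 to 3.35), the transporter gene araE at 0.883 (0.840 to 0.929) and the ribulokinase gene araB at 0.318 (0.282 to 0.359). The 8 maltose mRNAs had a median of -1.23 at percentile 32.4, with 2 at a ratio of 2 or more and 4 at 0.5 or less. The highest was malG, a transporter gene that overlaps the annotated sRNA malH, at 5.04 (3.20 to 8.87), named after its value was seen. The gene of maltose-binding protein, malE, stood at 0.219 (0.174 to 0.273), and malT and malP stood at 0.500 (0.418 to 0.601) and 0.234 (0.187 to 0.291).

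**Figure D3:**
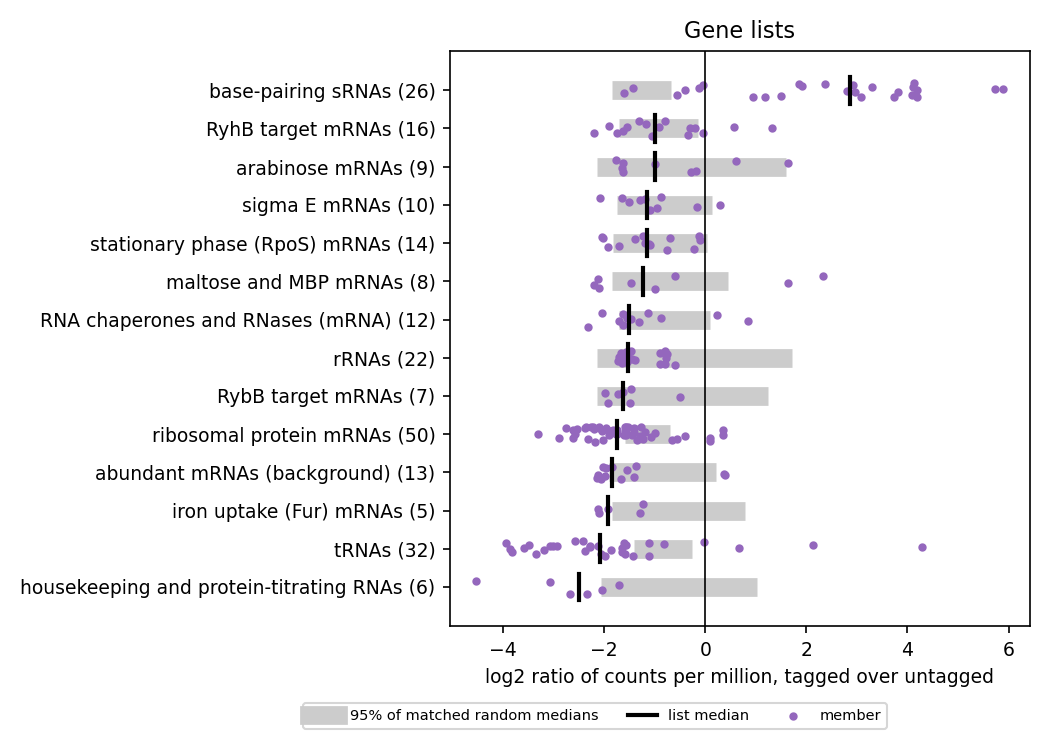
log2 ratio of CPM (tagged over untagged, x) for the members of each gene list past the count minimum (points; number in brackets), the list median (black bar) and the range that holds 95% of medians of expression-matched random lists (grey). The base-pairing sRNA median of 2.86 is above 0, and the medians of the other lists drawn are below 0.

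The ratios in the authors' deposited table use the authors' library totals and no pseudocount. In the authors' deposited table the ratio was 94.9 for omrB, 84.4 for rydC, 53.0 for aceK, 31.1 for leuZ, 30.9 for ryhB, 29.1 for rybB, 27.1 for arcZ, 26.8 for gcvB and 9.14 for the yecA_leuZ region.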

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

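The authors' library totals, the total without the bait region, listed counts of 1 set to 0 and the removal of read-sharing neighbours were chosen after the data were seen. The direction of the ryhB and rybB ratios and of the sRNA median was kept under every alternative run. With trimmed-mean scaling 338 features were enriched and 78 depleted, with median-of-ratios factors 349 and 72, with the mRNA total 303 and 109, and with the authors' library totals 312 and 101. Totals without tRNA and rRNA went the other way, with 155 and 531. All such settings multiply every ratio by 1 factor, so the order of features is untouched. They move the median log2 ratio of all features from -0.88 to -0.11, -0.08, -0.26, -0.22 and -1.09. The rybB ratio became 31.3, 32.0, 28.2, 28.9 and 15.8 in the same order. The ryhB ratio ran from 8.91 (pseudocount 5) to 30.4 (median-of-ratios factors) and stayed inside its interval, and the sRNA median ran from 2.38 to 3.66. A count minimum of 500 left 82 enriched and 111 depleted features, a ratio threshold of 2 gave 400 and 1221, and a threshold of 8 gave 88 and 53, by construction of the rule. Without the leuZ transcript and the bait region, the sRNA list took 13.4% of the tagged and 1.34% of the untagged counts. In all, 34 of 54 values stayed within their limits, and no ryhB or rybB ratio or sRNA median reversed. Counts of calls were not scored for reversal. The main run had more depleted than enriched features (381 and 184). That balance turned over with the trimmed-mean, median-of-ratios, mRNA-total and authors' scalings and with a threshold of 8. The analysis of each growth phase alone was not run, since the table does not hold the phases apart, and no replicate could be left out. No paired analysis was possible because each group has 1 library. Depth limits the untagged side most, where ryhB rests on 4 counts.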

Other observations

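The tests below were chosen after the results were seen, except that of protein-coding features that touch an enriched region. Several features outside the fixed lists hold sRNAs of the current annotation. Of these sRNAs, cpxQ, micL and rybA were on the fixed sRNA list but not in the table under their own names. Of 27 intergenic regions past the count minimum in which the reference places a noncoding RNA, leaving out the bait region, 13 had ratios of 2 or more and 8 of 0.5 or less, and 11 were enriched and 3 depleted by the rule. Their median log2 ratio of 0.90 lay at percentile 99.2 of expression-matched intergenic lists. The region with gadF (gadE_mdtE) stood at 30.4, that with glnZ, beside the glutamine synthetase gene (glnL_glnA), at 15.1 (14.1 to 16.2), that with kilS (kilR_sieB) at 13.1 (11.3 to 15.3), that with cpxQ, processed from the cpxP mRNA (cpxP_fieF), at 11.3 (9.73 to 13.3), that with xylZ (xylB_xylA) at 6.47 (6.17 to 6.80) and that with malH (xylE_malG) at 5.89 (5.47 to 6.36). The region with raiZ (raiA_pheL) had a lower ratio, 1.86 (1.81 to 1.92), at 24386 tagged counts. Others stood below 1. The region with micL (torY_cutC) stood at 0.696 (0.643 to 0.754). The regions with rybA stood at 0.499 (0.409 to 0.609) for ybiP_mntS and 0.111 (0.0804 to 0.148) for mntS_mntR.

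Enriched regions with no noncoding RNA in that annotation were abundant too. The region between yodB and serU had 16148 tagged counts, and the prophage region between xisE and ymfI had 15716 with a ratio of 9.36 (8.66 to 10.2). The region between treC and treB had 2734 and a ratio of 5.37 (4.65 to 6.25), and that between araF and ftnB 1838 and a ratio of 12.4 (9.60 to 16.6). These 4 were picked after their values were seen, for their depth and because they adjoin no listed sRNA and are in none of the 8 read-sharing pairs. The rule for those pairs, at least 500 tagged counts each and counts within 10%, does not detect partial sharing.

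The first pattern is the high ratio of base-pairing sRNAs. Whether the tagged library held a general surplus of short RNA stays open. The median log2 ratio of the 6 housekeeping RNAs minus that of all features was -1.62, with each one below that median. These stable RNAs were thus not raised, but RNA length was not compared, so they cannot decide the question for short RNA. A shift of all ratios by a few features that take most counts would move every feature alike. It would leave unchanged the gap of 3.74 in median log2 ratio between the list and all features. The lowest median of the list over the 6 other scalings was 2.65. That value is no test of such a shift, since each scaling multiplies every ratio by 1 factor. The lower bound for omrB was 62.3 times the upper bound for cyaR. These are the extremes of the 19 sRNAs with at least 500 counts over both libraries, and their bounds hold counting error alone. The comparison therefore leaves open whether all sRNAs were carried alike on a shared protein such as Hfq. Pairing with the bait, an unequal mix of the growth phases and chance differences between single libraries stay open too. The table has no bait mutant, other tagged RNA or separate phases to tell them apart.

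The second pattern is the 68 protein-coding features among the enriched, of which 4 hold an annotated sRNA: aceK with aceK-int, arcB with arcZ, ybiC with zbiJ and malG with malH. The counts of arcB differ from those of arcZ by at most 4.07%, so this pair largely shares its reads. For the others this stays open: the 30 protein-coding features with an annotated noncoding RNA lay at percentile 99.2 of matched mRNA lists, but their median log2 ratio was only -0.39, with 14 at 0.5 or less and 4 depleted, and ybiC and malG adjoin enriched regions with the same sRNA (ybiC_ybiJ and xylE_malG). The other 64 (94.1%) hold none, which does not exclude an annotated sRNA next to the gene, as with cpxP beside cpxQ, and 19 of them touch an enriched intergenic region (29.7%), against 4.56% of the other 1776 protein-coding features, so reads running in from a neighbour may account for part of them; unannotated sRNAs and mRNA fragments bound to the bait were not tested.

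The third pattern is the low ratio beside the 7 small-subunit rRNA genes, from 0.0437 to 0.164. The summed ratio of the mature genes (0.350, 0.345 to 0.355) was 5.96 times that of the 7 regions (0.0588, 0.0571 to 0.0604). The sum over the regions is carried by those beside rrsH, rrsD and rrsG. The regions beside rrsB, rrsC and rrsA were closer to the mature genes, at 0.164 (0.144 to 0.187), 0.163 (0.143 to 0.185) and 0.155 (0.136 to 0.177). All 7 regions lay below the mature genes, which ran from 0.316 to 0.383. The pattern was picked because such regions had the lowest ratios, and the intervals hold counting error of single libraries. The comparison therefore cannot decide whether the untagged library held more rRNA of every kind. A larger share of exponential phase cells in the untagged eluate is a possible explanation: stationary phase mRNAs lay 0.60 above ribosomal protein mRNAs in median log2 ratio (bootstrap over genes 0.04 to 1.14). That gap comes from the low ribosomal protein mRNAs (percentile 0.04). The stationary phase mRNAs were not high themselves, with a median of -1.15 against -0.88 for all features, at percentile 57.2. Genes are not independent replicates, and dps goes against the explanation. The phases were not recorded apart, and a biological effect of the tag was not tested.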
